A study of Homo sapiens with 12 samples.

How the data were processed

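RNA-seq libraries of CCRF-CEM parent and SLFN11-knockout cells were compared after 6 h with 100 nM prexasertib or DMSO, 3 libraries per group and 12 in all. Total RNA was extracted with TRIzol and sequenced as pooled libraries on 1 paired-end HiSeq4000 run, per the labels' protocols. The reference build was hg19, and the tools named were Trim Galore 0.6.2, Trimmomatic 0.39, STAR 2.5.4a and Picard 2.9.2, per the submitters' processing notes, which give no roles or settings. The counter, the gene annotation, the strand setting and the treatment of duplicates were not given in the sources used here. Each deposited file held, for each gene, a read count and a TPM value (length-scaled transcript abundance) as the authors computed them, with separate exonic and intronic read counts and read counts of regions that overlap no other gene, per the file headers. Reads in regions shared by overlapping genes were counted for each of these genes in the deposited counts, as found by comparing columns. Genes without reads were not listed in a file and were taken as 0. Large counts were kept to 6 digits in the files. Since no strand setting was given, reads of a gene and of its antisense partner cannot be told apart, and genes with near-identical copies (histone genes, HSPA1A and HSPA1B, HSPA6 and HSPA7) are uncertain.

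Samples were grouped by the line and treatment labels of their records, and each file was taken from the record it is attached to. The library name in the title named a file of the other treatment of the same line in 12 of 12 records. Both assignments were computed, and the one by attachment is reported. The files listed 44183 features in all. Copies on the Y pseudoautosomal regions (36) were left out, which left 44147, and each file listed 32924 to 35839 features. Exonic reads summed to 47887791 to 77548202 per library. Coordinates are those of the files in hg19, with 1 added to starts. The reference annotation at hand was of another build and was not used for coordinates. No libraries agreed within sampling noise: chi-square per degree of freedom over genes lay between 4.54 and 37.98 within groups.

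Exonic counts were tested in R 4.3.3 with edgeR 4.0.16, on 23045 genes kept by filterByExpr (minimum count 10), with TMM factors, 1 model of 4 group means over the 12 libraries, robust quasi-likelihood dispersion and the quasi-likelihood F test. The contrasts were prexasertib against DMSO in each line, knockout against parent under each treatment, and their interaction. Genes were called at a Benjamini-Hochberg adjusted p of at most 0.05. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a contrast, and again with an estimated correlation. CPM values use TMM-scaled library sizes. Shares of intronic reads were compared with an exact two-sided permutation test. With 3 libraries against 3 its smallest p is 0.1.

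The 20 lists held 617 genes. Those reported are immediate early genes, NF-kappaB target genes, interferon-stimulated genes, DNA replication and G1/S genes, G2/M genes, DNA damage checkpoint and homologous recombination genes, replication-dependent histone genes, ATF4 and unfolded protein response genes, heat shock genes, BCL2 family genes, cholesterol synthesis genes, MYC target and ribosome biogenesis genes, Schlafen family genes, T-lineage genes, MHC genes, cytosolic ribosomal protein genes, mitochondrially encoded mRNAs, B-cell and myeloid markers, and epithelial, fibroblast and erythroid markers. They were written from general knowledge, and some share members, such as MCL1. Some results that the rules above and below cover are not reported here. Some members were not listed in the files under the symbols used, among them DUSP5. IL8 is the files' symbol for CXCL8.

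Genes were named by a fixed rule. For each contrast it took the 5 higher and 5 lower genes with the largest log2 fold change among those called, with a mean log2 CPM of at least 1 and no overlap between the groups (the last not asked of the interaction). It also took the 4 immediate early genes with the smallest p, the 2 genes with the smallest p of every other list except the marker, ribosomal protein and mitochondrial ones, and SLFN11. CPM levels of such genes are also given in other groups. Small nucleolar RNAs, pseudogenes and unnamed transcripts that the rule took are left out of the text.

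The test was checked on simulated counts with 50 genes changed at each fold. For parent cells it recovered 40, 82, 88 and 100% of genes changed 1.25, 1.5, 2 and 4-fold among 22555 genes, with 9 false calls of 164. For knockout cells it recovered 42, 76, 96 and 100% among 22571 genes, with 9 false of 166. For the lines under DMSO it recovered 46, 82, 96 and 100% among 22543 genes, with 16 false of 178. For the lines under prexasertib it recovered 54, 76, 94 and 100% among 22551 genes, with 11 false of 173. For the interaction it recovered 12, 60, 76 and 96% among 22580 genes, with 8 false of 130. Far fewer genes were changed in the simulated counts than were called in the data, where contrasts called 12.94 to 39.97% of genes. Recovery and false calls at such shares were not tested. The changed genes were drawn only from those above a minimum mean expression. Recovery was not split by expression level either, so it is not known for genes with few reads. The percentages are thus not the power or error rate of the tests on the data.

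Alternatives to these choices were RLE factors, total counts only, no filter on low counts, a mean CPM of at least 1, DESeq2 1.42.0, all reads of a gene with introns, exonic reads that overlap no other gene, limma 3.58.1 on log2(TPM + 1) of the deposited TPM, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, an adjusted p of at most 0.01, a test against 1.5-fold (glmTreat), files assigned by library name, and intron shares without the 100 genes with most reads. Their effects are given in the closing section.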

Results

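RNA from CCRF-CEM cells, an established T lymphoblast leukemia line, was sequenced in the parent line and in a line whose SLFN11 gene was knocked out. SLFN11 is a Schlafen family protein that acts on stalled replication forks. Both lines were cultured for 6 h with 100 nM prexasertib, an inhibitor of the checkpoint kinase CHK1, or with its solvent DMSO. The 4 groups held 3 libraries each, 12 in all, with 47887791 to 77548202 exonic reads per library. The series title gives the question as immediate early gene activation by SLFN11 under replication stress. That question concerns the effect of prexasertib in each line, the effect of the knockout under each treatment, and the difference between the lines in the effect of prexasertib. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

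The records and the files conflict over treatment. In 12 of 12 records the library name in the title was that of a file attached to the other treatment of the same line. Values are given here by the record a file is attached to, as "labelled prexasertib" and "labelled DMSO". If the library names hold instead, each treatment difference and the difference between the lines in it change sign, and the comparisons of the lines under labelled DMSO and labelled prexasertib change places. The gene lists, the tests and the rule for naming genes were fixed before the data were examined. In every contrast 23045 genes were tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment, at an adjusted p of at most 0.05.

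SLFN11 lies on chromosome 17 at 33677324 to 33700720 in hg19. Its RNA was lower in knockout than in parent cells but was still read in each knockout library. In the parent libraries labelled DMSO it had 100, 91.2 and 95.2 CPM (read counts scaled to the size of the library), a mean of 95.6 ± 4.65 (SD, n = 3). In those labelled prexasertib it had 117, 119 and 117 CPM, a mean of 117 ± 1.31 (SD, n = 3). The knockout libraries had 65.9, 66.6 and 69.1 CPM when labelled DMSO, a mean of 67.2 ± 1.68 (SD, n = 3). They had 85.0, 90.7 and 89.4 CPM when labelled prexasertib, a mean of 88.4 ± 3.0 (SD, n = 3). The log2 fold change of knockout against parent was -0.51 (SE 0.05, edgeR adjusted p = 6.0e-09) under labelled DMSO and -0.41 (SE 0.05, edgeR adjusted p = 5.5e-07) under labelled prexasertib. Introns held 27.4 to 31.5% of SLFN11 reads in knockout libraries and 15.95 to 19.73% in parent libraries. A disrupted gene can still be transcribed, so this RNA level is a weak check of the line labels, and it says nothing about the treatment labels.

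In parent cells, immediate early genes, genes of the G2 and M phases, NF-kappaB targets and replication-dependent histone genes had lower RNA in labelled prexasertib, whose files carry the DMSO library names, and most heat shock genes had higher RNA. JUN, a subunit of the AP-1 transcription factor, went from 530 ± 18.7 CPM in labelled DMSO to 59.1 ± 2.41 CPM in labelled prexasertib (mean ± SD, n = 3 each), a log2 fold change of -3.17 (SE 0.06). The stress-induced transcription factor gene ATF3 differed by -3.39 (SE 0.07), and the CDK inhibitor gene CDKN1A by -2.90 (SE 0.10). AURKA, the mitotic Aurora A kinase gene, went from 614 to 124 CPM and differed by -2.31 (SE 0.06). All 4 passed at edgeR adjusted p values of 3.05e-18 or smaller. In all, 4183 genes were higher and 4191 were lower, of which 259 and 772 differed at least 2-fold. The groups did not overlap for 43.3% of genes, where chance gives 10%.

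Of 41 immediate early genes, which respond to stimuli without new protein synthesis, 36 were lower and 2 were higher, and the counts adjusted over the list alone were the same. Their median log2 fold change was -1.71 (camera adjusted p = 4.3e-86), or -0.87 on the log2(TPM + 1) scale, which shrinks the changes of low genes. MYC and KLF2 were the 2 higher members, named after their values were seen. KLF6 differed by -2.18 (SE 0.06) and the antiproliferative gene BTG2 by -2.31 (SE 0.07). DUSP8, a phosphatase gene of stress kinase signaling, was among the most changed genes at -5.69 (SE 0.14), with 32.7 CPM in labelled DMSO and 0.637 CPM in labelled prexasertib. The nuclear receptor gene NR4A3 differed by -4.04 (SE 0.17), and the chemokine gene IL8 (CXCL8) by -4.40 (SE 0.25). Of 21 NF-kappaB targets, 20 were lower and none was higher by edgeR, with the same counts when adjusted over the list alone, and the median was -1.27 (camera adjusted p = 5.3e-54). NFKB2, a subunit gene of the factor, differed by -2.91 (SE 0.08), and NFKBIA, the gene of its inhibitor, by -1.98 (SE 0.06).

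**Figure D1:**
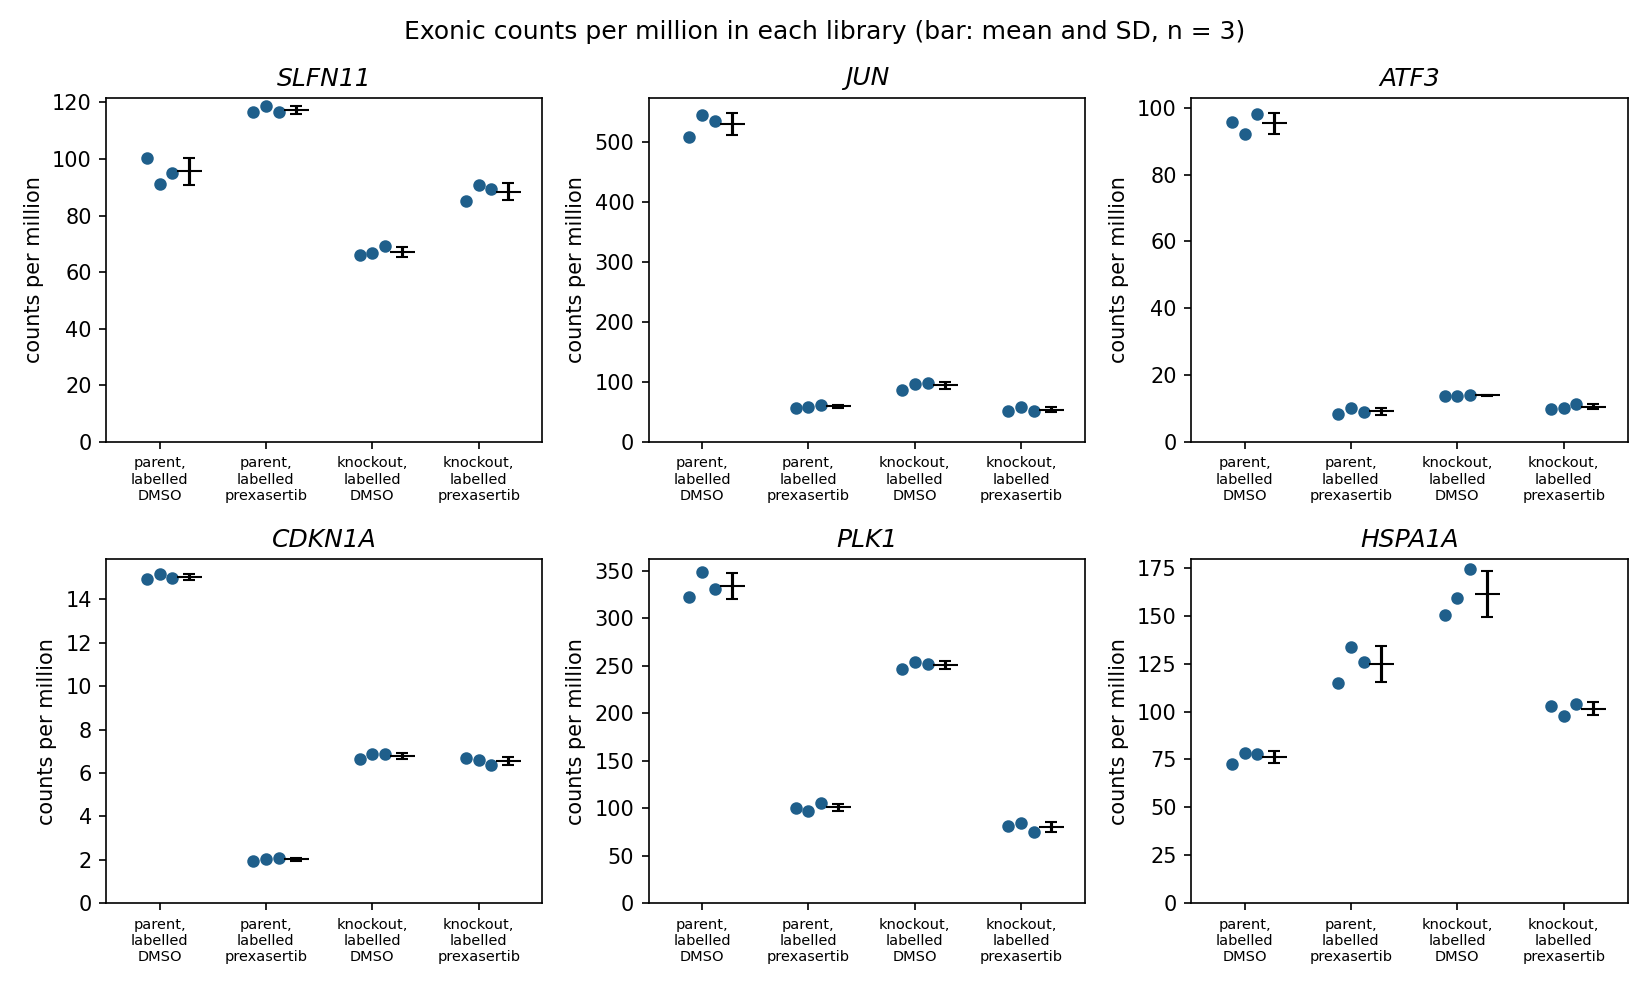
CPM of SLFN11, JUN, ATF3, CDKN1A, PLK1 and HSPA1A in each of the 12 libraries (points), with the mean and SD of the 3 libraries of each group. JUN averaged 530 CPM in the parent libraries labelled DMSO, whose files carry the prexasertib names, and between 53.7 and 94.2 CPM in the other groups.

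Cell cycle genes also differed in parent cells. Of 41 G2/M genes, 40 were lower in labelled prexasertib, also when adjusted over the list alone, with a median of -1.13 (camera adjusted p = 7.1e-148). The kinetochore motor gene CENPE differed by -1.96 (SE 0.05). PLK1, the polo-like kinase gene on chromosome 16 at 23688977 to 23701688, averaged 334 CPM in labelled DMSO and 101 CPM in labelled prexasertib. Of 54 replication-dependent histone genes, 53 were lower, also when adjusted over the list alone, with a median of -0.87 (camera adjusted p = 3.8e-68). HIST1H2AC, at -1.48 (SE 0.06), and the other histone genes share reads with near-identical copies and are uncertain one by one. Heat shock genes were higher for 20 of 25 and lower for 2 (20 and 3 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 4.8e-10). The chaperone genes HSPH1 and HSPA8 each differed by 0.74 (SE 0.05 and 0.06). The immediate early, NF-kappaB, G2/M, histone and heat shock lists also passed with an estimated correlation, at adjusted p values of 4.4e-05 to 0.039.

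The other lists that passed in parent cells did so only with the preset correlation. Cholesterol synthesis genes were lower for 16 of 24 and higher for 6 (17 and 6 adjusted over the list alone), with a median of -0.38 (-0.20 with the authors' TPM) and adjusted p = 0.18 with an estimated correlation. HMGCS1, an early enzyme gene of the pathway, differed by -0.75 (SE 0.05). MYC target and ribosome biogenesis genes were higher for 16 of 33 and lower for 2 (19 and 2 adjusted over the list alone), with adjusted p = 0.38 with an estimated correlation. DNA replication and G1/S genes were higher for 23 of 50 and lower for 6 (25 and 7 adjusted over the list alone), with adjusted p = 0.54 with an estimated correlation. This call was also lost without labelled DMSO replicate 1 or labelled prexasertib replicate 3 (both adjusted p = 0.052). T-lineage genes were higher for 22 of 42 and lower for 8 (25 and 8 adjusted over the list alone), with adjusted p = 0.11 with an estimated correlation, 0.093 without labelled DMSO replicate 1 and 0.061 in a fit of only the parent groups. BCL2 family genes were higher for 5 of 17 and lower for 6, the same adjusted over the list alone, with adjusted p = 0.38 with an estimated correlation and 0.079 with the authors' TPM. MCL1, an antiapoptotic member, differed by -1.07 (SE 0.05), and PMAIP1, a proapoptotic one, by -1.20 (SE 0.07). Of genes in lists that did not pass, WEE1, the kinase gene of the G2/M checkpoint, differed by -0.74 (SE 0.05), RPA1, a gene of the single-stranded DNA binding complex, by 0.75 (SE 0.06), and DDIT3, a gene of the unfolded protein response, by -1.45 (SE 0.06). Introns held 27.5 ± 2.39% of gene reads in the parent libraries labelled prexasertib and 24.6 ± 0.86% in those labelled DMSO (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). One library, labelled prexasertib replicate 1, stood at 30.3%.

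In knockout cells, G2/M genes, cholesterol synthesis genes, immediate early genes and NF-kappaB targets had lower RNA in labelled prexasertib, whose files again carry the DMSO library names. PLK1 went from 251 ± 4.11 CPM to 80.1 ± 5.0 CPM (mean ± SD, n = 3 each), a log2 fold change of -1.65 (SE 0.05). PIF1, a DNA helicase gene, differed by -2.39 (SE 0.06) and the mitotic activator gene CDC20 by -1.53 (SE 0.05). JUN went from 94.2 ± 5.97 to 53.7 ± 3.89 CPM and differed by -0.81 (SE 0.06, edgeR adjusted p = 1.1e-10). ADM, the gene of the peptide hormone adrenomedullin, was higher at 7.50 against 2.55 CPM, a log2 fold change of 1.56 (SE 0.14). In all, 1407 genes were higher and 1575 were lower, of which 42 and 172 differed at least 2-fold. The groups did not overlap for 34.3% of genes, where chance gives 10%. The count of higher genes was 922 without labelled prexasertib replicate 1, 926 without labelled DMSO replicate 2 and 857 without labelled DMSO replicate 3, and that of lower genes was 1048 without the last.

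As in parent cells, 40 of 41 G2/M genes were lower, also when adjusted over the list alone, with a median of -0.79 (camera adjusted p = 1.8e-226). Of 24 cholesterol synthesis genes, 19 were lower (20 adjusted over the list alone) and none was higher by edgeR, with a median of -0.31 (camera adjusted p = 2.8e-23). HMGCS1 differed by -0.65 (SE 0.05). Of the 41 immediate early genes, 23 were lower and 2 higher (25 and 2 adjusted over the list alone), with a median of -0.31 (-0.19 with the authors' TPM, camera adjusted p = 5.3e-23). Among them were PPP1R15A, a phosphatase subunit gene of the stress response, at -1.60 (SE 0.07), IER5 at -0.81 (SE 0.06), and DUSP1 at -1.04 (SE 0.08), the last with too few reads outside other genes for a test of those alone. Of 21 NF-kappaB targets, 12 were lower (14 adjusted over the list alone) and none higher, with a median of -0.26 (camera adjusted p = 1.7e-13). NFKB2 differed by -0.87 (SE 0.08) and NFKBIA by -0.65 (SE 0.06). These 4 lists passed with an estimated correlation too, at adjusted p values of 0.00014 to 0.0054.

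Heat shock genes were lower for 10 of 25 in knockout cells and higher for none (11 and 3 adjusted over the list alone), with adjusted p = 0.057 with an estimated correlation. The median of -0.07 was -0.13, -0.02 and -0.12 without labelled prexasertib replicates 1, 2 and 3, -0.02 with the authors' TPM, -0.14 with all reads and -0.16 with reads outside other genes. HSPA1A, an inducible chaperone gene, differed by -0.67 (SE 0.06) and the related HSPA6 by -1.46 (SE 0.06). Both have near-identical copies and are uncertain. Histone genes were higher for 3 of 54 and lower for 10 (3 and 11 adjusted over the list alone) and did not pass (camera adjusted p = 0.10). DNA replication and G1/S genes were higher for 20 of 50 and lower for 1 (26 and 3 adjusted over the list alone), with adjusted p = 0.18 with an estimated correlation. Examples were the cyclin gene CCNE2 at 0.83 (SE 0.06) and the ribonucleotide reductase gene RRM2 at 0.61 (SE 0.05). Of the MYC target list 8 of 33 were higher (13 adjusted over the list alone), with adjusted p = 0.24 with an estimated correlation. DNA damage checkpoint and homologous recombination genes were higher for 9 of 44 and lower for 2 (12 and 2 adjusted over the list alone), with adjusted p = 0.27 with an estimated correlation. ATF4 and unfolded protein response genes were higher for 9 of 29 and lower for 2 (10 and 4 adjusted over the list alone), with adjusted p = 0.15 with an estimated correlation. The chaperone regulator gene XBP1 differed by 0.47 (SE 0.05). Interferon-stimulated genes were lower for 8 of 32 and higher for 4 (9 and 4 adjusted over the list alone), with adjusted p = 0.055 with an estimated correlation, 0.42 with reads outside other genes and 0.057 with a mean CPM of at least 1. IFIT1 differed by -1.37 (SE 0.16), also with too few reads outside other genes for a test of those alone. Introns held 25.8 ± 0.29% of gene reads in labelled prexasertib and 25.5 ± 0.46% in labelled DMSO (SD, n = 3 each, exact two-sided permutation p = 0.5, smallest possible 0.1).

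The difference between the lines in the response was tested as the interaction, the log2 fold change in parent cells less that in knockout cells. JUN differed by -2.36 (SE 0.08), ATF3 by -2.99 (SE 0.10), CDKN1A by -2.85 (SE 0.13) and DUSP8 by -4.99 (SE 0.20). JUN, ATF3 and DUSP8 were lower by more in parent than in knockout libraries labelled prexasertib, whose files carry the DMSO names. CDKN1A was lower in these parent libraries but near level in knockout cells, at 6.79 CPM in labelled DMSO and 6.55 CPM in labelled prexasertib. HSPA1A differed by 1.38 (SE 0.08) and HSPA6 by 2.21 (SE 0.09), both higher in labelled prexasertib in parent cells and lower in it in knockout cells. HSPA1A averaged 76.3 and 125 CPM in parent cells labelled DMSO and prexasertib, and 162 and 102 CPM in knockout cells. All 6 passed at edgeR adjusted p values of 6.94e-12 or smaller. The interaction passed for 3883 genes, 1686 above 0 and 2197 below 0, of which 97 and 318 differed at least 2-fold. The count above 0 was 954 without parent labelled DMSO replicate 1, 1069 without knockout labelled prexasertib replicate 3, and 1023 and 1017 without knockout labelled DMSO replicates 1 and 2.

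Of the 41 immediate early genes, 28 had an interaction below 0 and 2 above 0 (30 and 2 adjusted over the list alone), with a median of -1.30 (-0.58 with the authors' TPM, camera adjusted p = 2.9e-69). The log2 fold change lay further from 0 in parent cells for 37 of the 41, and 23 were lower in both lines. KLF6 differed by -1.72 (SE 0.08), BTG2 by -2.15 (SE 0.10) and IL8 by -3.72 (SE 0.52), the last with 0.330 CPM or less in knockout groups. NF-kappaB targets had 15 of 21 below 0 (16 adjusted over the list alone) and a median of -0.89 (camera adjusted p = 6.6e-39), with NFKB2 at -2.04 (SE 0.11) and BIRC3, an apoptosis inhibitor gene, at -1.54 (SE 0.09). Histone genes had 51 of 54 below 0 (54 adjusted over the list alone) and a median of -0.77 (camera adjusted p = 5.3e-91), with HIST1H2AC at -1.42 (SE 0.08). G2/M genes had 29 of 41 below 0 (31 adjusted over the list alone) and a median of -0.40 (camera adjusted p = 3.0e-25). The phosphatase gene CDC25C differed by -1.09 (SE 0.08) and AURKA by -0.95 (SE 0.08). Heat shock genes had 17 of 25 above 0 and 1 below (18 and 1 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 4.7e-32), and SERPINH1, a collagen chaperone gene, differed by 1.82 (SE 0.14). These 5 lists also passed with an estimated correlation, at adjusted p values of 9.7e-05 to 0.034.

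**Figure D2:**
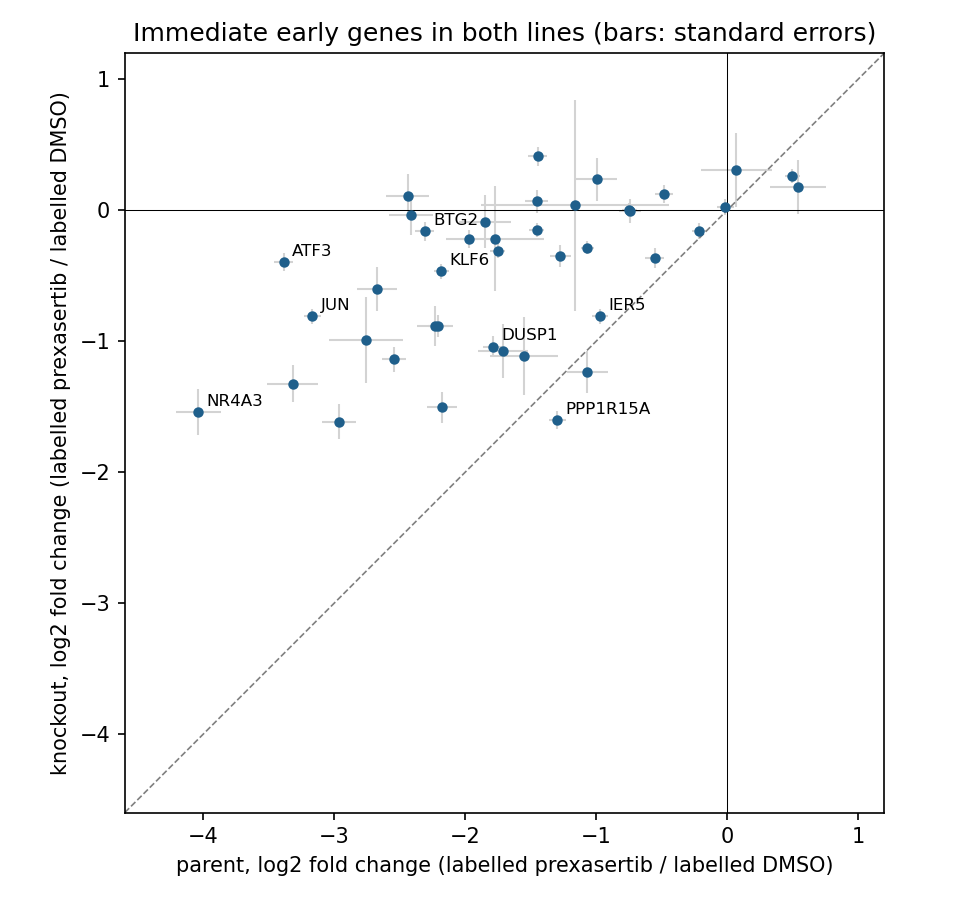
Log2 fold change (labelled prexasertib over labelled DMSO) of the 41 tested immediate early genes in parent cells (x axis) and knockout cells (y axis), with standard errors and a dashed line of equality. The parent value lay further from 0 for 37 genes, and all signs reverse if the library names in the titles hold.

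Weaker lists passed for the interaction only with the preset correlation. ATF4 and unfolded protein response genes had 11 of 29 below 0 and 5 above, the same adjusted over the list alone, with adjusted p = 0.091 with an estimated correlation, and DDIT3 differed by -1.54 (SE 0.09). DNA damage checkpoint and homologous recombination genes had 13 of 44 below 0 and 2 above, the same adjusted over the list alone, with adjusted p = 0.48 with an estimated correlation. Their call was also lost with the authors' TPM (median 0.054, adjusted p = 0.26), total counts only (-0.0091, 0.093), all reads (-0.072, 0.060), reads outside other genes (-0.065, 0.075) and a mean CPM of at least 1 (-0.085, 0.072). The median of -0.07 was -0.13, -0.10 and -0.11 without parent labelled DMSO replicate 2, knockout labelled prexasertib replicate 2 and knockout labelled DMSO replicate 1. BRCA2, a homologous recombination gene, differed by -0.66 (SE 0.08) and RPA1 by 0.68 (SE 0.08). BCL2 family genes had 5 of 17 below 0 and 2 above (5 and 3 adjusted over the list alone), with adjusted p = 0.48 with an estimated correlation. Their median of 0.02 and mean of -0.27 differed in sign, and the median ran from -0.10 to 0.02 with a library left out. The call was lost without parent labelled prexasertib replicate 1 (median -0.10, camera adjusted p = 0.081), parent labelled DMSO replicate 2 (-0.012, 0.069) or knockout labelled prexasertib replicate 1 (0.020, 0.054), and with DESeq2 (0.0095, 0.050), all reads (-0.13, 0.052), no filter on low counts (0.018, 0.061), a mean CPM of at least 1 (-0.0039, 0.075), reads outside other genes (-0.021, 0.068), the replicate number as a block (0.0081, 0.053) and the authors' TPM (0.040, 0.15). MCL1 differed by -0.78 (SE 0.07) and PMAIP1 by -0.99 (SE 0.09). Outside these lists, the sterol synthesis gene LSS differed by 0.90 (SE 0.08) and HES1, a target of Notch signaling, by -0.82 (SE 0.08). For SLFN11 itself the interaction was -0.10 (SE 0.07) and did not pass (edgeR adjusted p = 0.39).

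Across genes the responses of the lines overlapped. Both lines had 912 genes higher in common, where independent lists would share 255.4, and 1090 lower, where they would share 286.4. Opposite calls numbered 70 and 67, against 285.9 and 255.9 for independent lists. These comparisons share no library. Across the 23045 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.348 and a Spearman rho of 0.356, and the slope of knockout on parent was 0.239. Of 6235 genes that passed in parent cells but not in knockout cells, the interaction passed for 2702.

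**Figure D3:**
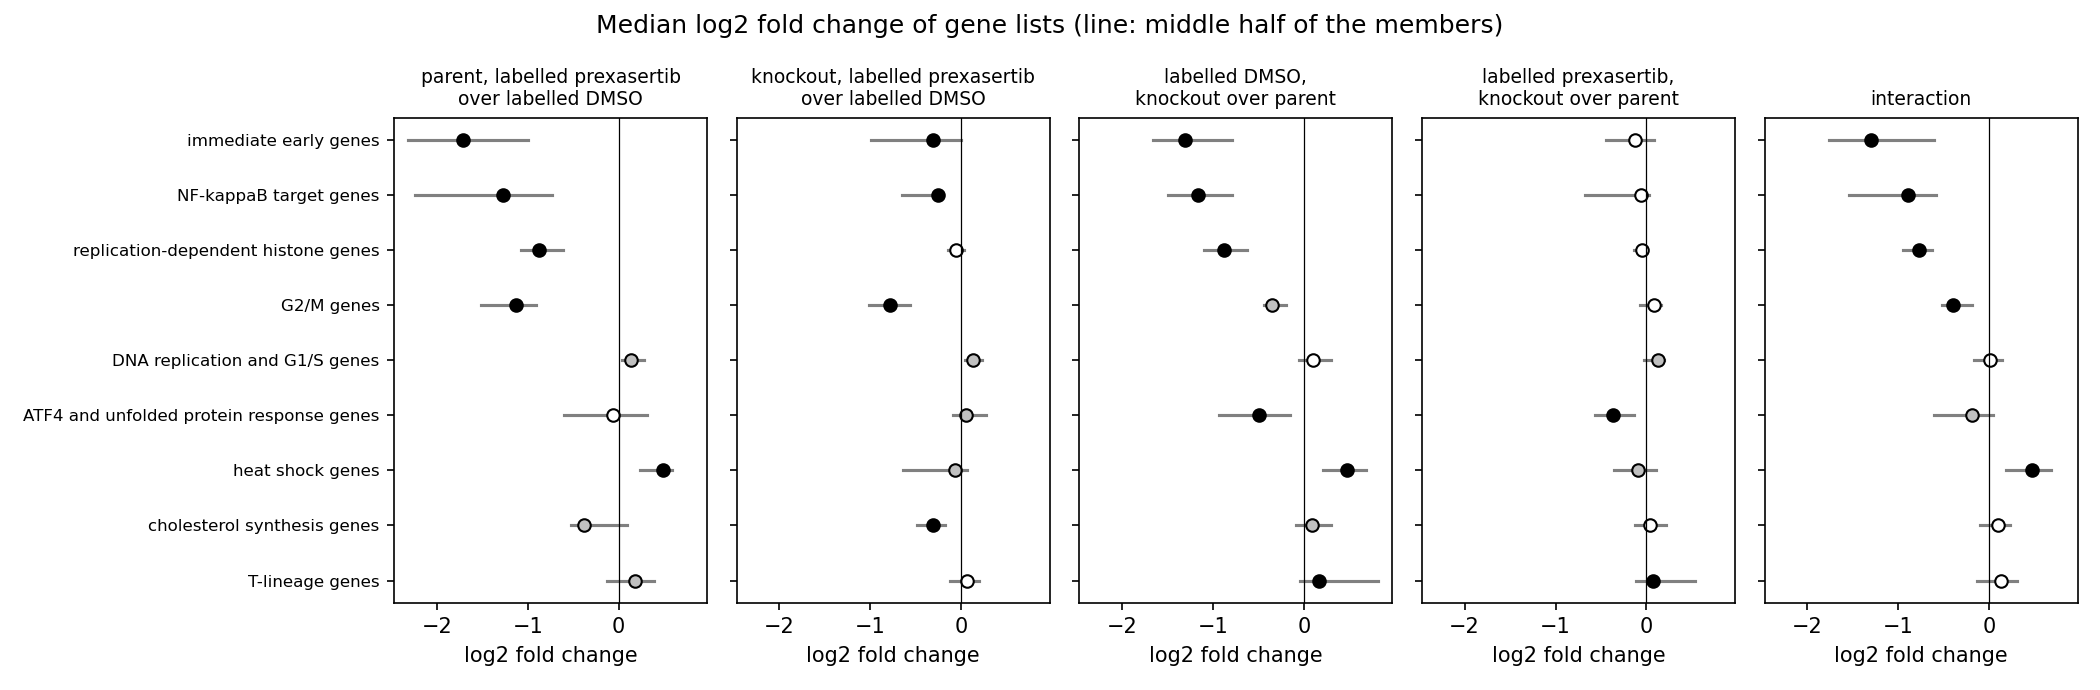
Median log2 fold change of 9 gene lists (points) with the range between the quartiles of members (lines) in the 5 contrasts, filled where the camera test passed with a preset and an estimated correlation, grey where it passed with the preset one, open where it did not pass. The immediate early list had medians of -1.71 in parent cells and -0.31 in knockout cells. With the authors' TPM the heat shock and immediate early medians between the lines under labelled prexasertib turn above 0. If the library names in the titles hold, treatment and interaction signs reverse and the panels that compare the lines change places.

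Under labelled DMSO, whose files carry the prexasertib library names, knockout cells had lower RNA of immediate early, NF-kappaB target, histone and ATF4 pathway genes than parent cells, and higher RNA of heat shock and T-lineage genes. That comparison used the same parent libraries labelled DMSO as the treatment comparison in parent cells and the interaction. Results that these contrasts have in common are therefore not separate evidence. JUN averaged 530 CPM in those libraries and 53.7 to 94.2 CPM in the other groups. ARHGEF12, a nucleotide exchange factor gene on chromosome 11 at 120207787 to 120360645, averaged 8.29 CPM in parent and 0.058 CPM in knockout libraries, a log2 fold change of -7.06 (SE 0.23). CDC42BPA, a kinase gene of the cytoskeleton, differed by -5.28 (SE 0.19), while LRRC6 differed by 4.86 (SE 0.18) and the transcription factor gene KLF3 by 3.50 (SE 0.19). JUN differed by -2.49 (SE 0.06, edgeR adjusted p = 1.1e-20). In all, 4515 genes were higher and 4697 lower in knockout cells, of which 650 and 979 differed at least 2-fold, and the groups did not overlap for 53.6% of genes, where chance gives 10%.

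Of the immediate early genes, 34 of 41 were lower and 2 higher in knockout cells under labelled DMSO, the same adjusted over the list alone, with a median of -1.31 (-0.54 with the authors' TPM, camera adjusted p = 1.1e-50). ATF3 differed by -2.78 (SE 0.07), JUND by -1.66 (SE 0.06) and BTG2 by -2.05 (SE 0.07). NF-kappaB targets were lower for 19 of 21 and higher for 1, the same adjusted over the list alone, with a median of -1.17 (-0.56 with the authors' TPM, camera adjusted p = 1.5e-34), and NFKB1 differed by -1.50 (SE 0.06). All 54 histone genes were lower, also adjusted over the list alone, with a median of -0.88 (camera adjusted p = 1.5e-65). ATF4 and unfolded protein response genes were lower for 21 of 29 and higher for 3, the same adjusted over the list alone, with a median of -0.49 (-0.13 with the authors' TPM, camera adjusted p = 8.8e-14). Among them were DDIT3 at -1.69 (SE 0.06) and the cystine transporter gene SLC7A11 at -1.54 (SE 0.08). Heat shock genes were higher for 20 of 25 and lower for 2, the same adjusted over the list alone, with a median of 0.48 (0.72 with the authors' TPM, camera adjusted p = 1.1e-11). T-lineage genes were higher for 20 of 42 and lower for 8, the same adjusted over the list alone, with a median of 0.16 (camera adjusted p = 3.5e-06), which was 0.099 without parent labelled DMSO replicate 1 and 0.43 with the authors' TPM. The cortical thymocyte gene CD1A differed by 1.71 (SE 0.07). These 6 lists also passed with an estimated correlation, at adjusted p values of 0.00021 to 0.024. G2/M genes were lower for 32 of 41 and higher for 2 (32 and 3 adjusted over the list alone), with adjusted p = 0.16 with an estimated correlation. Cholesterol synthesis genes were higher for 10 of 24 and lower for 3 (10 and 4 adjusted over the list alone), with adjusted p = 0.45 with an estimated correlation. This call was also lost without parent labelled DMSO replicate 1 (adjusted p = 0.063) or knockout labelled DMSO replicates 1 (0.054) or 2 (0.055), with reads outside other genes (0.068) and with a mean CPM of at least 1 (0.11). Introns held 25.5 ± 0.46% of gene reads in knockout and 24.6 ± 0.86% in parent libraries (SD, n = 3 each, exact two-sided permutation p = 0.2, smallest possible 0.1).

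Under labelled prexasertib, whose files carry the DMSO library names, knockout cells again had lower ATF4 pathway RNA and higher T-lineage RNA, while the immediate early genes as a list did not pass. ARHGEF12 averaged 8.02 CPM in parent and 0.012 CPM in knockout libraries. CDC42BPA averaged 10.7 and 0.130 CPM, a log2 fold change of -6.34 (SE 0.22). The granzyme gene GZMA differed by -3.93 (SE 0.12), LRRC6 by 6.22 (SE 0.21), KLF3 by 5.92 (SE 0.27) and the phosphodiesterase gene PDE10A by 3.42 (SE 0.16). HLA-B, an MHC class I gene, averaged 109 CPM in parent and 57.4 CPM in knockout libraries and differed by -0.92 (SE 0.05, edgeR adjusted p = 4.3e-13). In all, 3349 genes were higher and 3118 lower, of which 553 and 642 differed at least 2-fold, and the groups did not overlap for 38.1% of genes, where chance gives 10%.

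Immediate early genes under labelled prexasertib were higher for 6 of 41 and lower for 12 in knockout cells, the same adjusted over the list alone, with a median of -0.13 (0.014 with the authors' TPM) that did not pass (camera adjusted p = 0.21). RHOB, a small GTPase gene, differed by 3.01 (SE 0.20) and KLF6 by 1.28 (SE 0.06), while PPP1R15A differed by -1.14 (SE 0.07). ATF4 and unfolded protein response genes were lower for 21 of 29 and higher for 2 (22 and 2 adjusted over the list alone), with a median of -0.37 (-0.13 with the authors' TPM, camera adjusted p = 5.3e-09). SLC7A11 differed by -0.82 (SE 0.08). T-lineage genes were higher for 18 of 42 and lower for 7 (18 and 8 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 5.4e-05), and THEMIS, a thymocyte selection gene, differed by 1.08 (SE 0.05). That median was 0.11 and 0.041 without parent labelled prexasertib replicates 1 and 2, 0.041 without knockout labelled prexasertib replicate 1, and 0.22 with the authors' TPM. Both lists passed with an estimated correlation too, at adjusted p = 0.018. DNA replication and G1/S genes were higher for 23 of 50 and lower for 4 (27 and 4 adjusted over the list alone), with adjusted p = 0.54 with an estimated correlation. Heat shock genes were lower for 9 of 25 and higher for 3, the same adjusted over the list alone, with a median of -0.10 (0.055 with the authors' TPM) and adjusted p = 0.41 with an estimated correlation. The call was lost without parent labelled prexasertib replicate 2 (median -0.11, adjusted p = 0.050), with reads outside other genes (-0.12, 0.10) and with the authors' TPM (adjusted p = 0.26), and the median was -0.06 without replicate 3 of that group. HIST1H1A differed by -3.57 (SE 0.30), and the histone list did not pass (camera adjusted p = 0.10). Introns held 25.8 ± 0.29% of gene reads in knockout and 27.5 ± 2.39% in parent libraries (SD, n = 3 each, exact two-sided permutation p = 0.2, smallest possible 0.1).

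The differences between the lines overlapped across the labelled treatments. Of the genes called under both, 2197 were higher and 1758 lower in knockout cells each time, where independent lists would share 656.1 and 635.5, and 385 were called in opposite directions. These comparisons also share no library. Across genes, which are not independent replicates, Pearson's r was 0.615 and Spearman's rho 0.455. SLFN5, a neighbor of SLFN11 in the same family, was higher in knockout cells by 0.66 (SE 0.05) under labelled DMSO and 0.78 (SE 0.05) under labelled prexasertib. SLFN12 differed by -1.06 (SE 0.11) under labelled prexasertib. Of 5 Schlafen genes, 4 were lower and 1 higher in knockout cells under both labelled treatments, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.16 and 0.11).

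Lists of markers of other cell types, of ribosomal proteins and of mitochondrial mRNAs passed in none of the 5 contrasts by camera. Of 9 tested B-cell and myeloid markers, 2 were higher in labelled prexasertib in parent cells and none passed in knockout cells, while 4 were lower in knockout than in parent cells under each labelled treatment and 2 and 1 were higher. Of 7 tested epithelial, fibroblast and erythroid markers, none differed between treatments in parent cells and 1 was lower in knockout cells in labelled prexasertib. Between the lines 2 of the 7 were higher and 1 lower under labelled DMSO, and 1 was higher and 1 lower under labelled prexasertib. Of 43 ribosomal protein genes, 3 were higher in labelled prexasertib in parent cells and none passed in knockout cells. Between the lines 6 were lower and 2 higher under labelled DMSO, and 10 were lower and 2 higher under labelled prexasertib. Of 13 mitochondrial mRNAs, 2 were higher in labelled prexasertib in parent cells and none passed in knockout cells. Adjusted over the list alone, these counts were the same except that in parent cells 1 ribosomal protein gene and no mitochondrial mRNA passed, and that 1 ribosomal protein gene was higher and 1 lower between the lines under labelled DMSO. MHC genes passed in no contrast either, with 6 of 17 higher and 2 lower in labelled prexasertib in parent cells, also when adjusted over the list alone. Interferon-stimulated genes did not pass in parent cells, where 8 of 32 were higher and 12 lower, also when adjusted over the list alone.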

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

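The values without a library and with total counts only were planned as alternatives, but their use in this part as tests of an explanation was chosen after the interaction values had been seen, as were the thinning of the libraries, which was not planned, and the grouping of the redrawn interaction splits by line. The difference between the lines in the response to the labelled treatment was tested as an interaction, and results that passed it are given here. It passed for 3883 genes. The list medians of the interaction (parent less knockout log2 fold change) were -0.77 for histone genes, -1.30 for immediate early genes (-0.58 with the authors' TPM), -0.89 for NF-kappaB targets, 0.47 for heat shock genes, -0.40 for G2/M genes, -0.19 for ATF4 and unfolded protein response genes (-0.06 with the authors' TPM), -0.0667 for DNA damage checkpoint genes (0.054 with the authors' TPM, -0.0091 with total counts only) and 0.0171 for BCL2 family genes, whose median lay between -0.103 and 0.02012 with a library left out and whose call 3 of those fits lost. The last 3 lists did not pass with an estimated correlation, at adjusted p = 0.091, 0.48 and 0.48. Among genes, the interaction was 2.21 for HSPA6, 1.38 for HSPA1A, 1.82 for SERPINH1, 0.90 for LSS and 0.68 for RPA1. It was -4.99 for DUSP8, -3.72 for IL8, -2.99 for ATF3, -2.85 for CDKN1A, -2.36 for JUN, -2.15 for BTG2, -2.04 for NFKB2, -1.72 for KLF6, -1.54 for BIRC3, -1.54 for DDIT3, -1.42 for HIST1H2AC, -1.09 for CDC25C, -0.99 for PMAIP1, -0.95 for AURKA, -0.82 for HES1, -0.78 for MCL1 and -0.66 for BRCA2.

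The library name in each title is that of a file attached to the other treatment of the same line. A deposit in which the files of the treatments were exchanged predicts a median of the immediate early list below 0 in parent cells, because the series title speaks of activation, and this prediction was made before the value was seen. The median was -1.711, with 36 of 41 members lower and 2 higher, which is consistent with exchanged files. The prediction rests on the title's claim, so a true fall of these genes under prexasertib with correct attachments stays open. SLFN11 levels bear on the line labels alone and cannot settle it.

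The immediate early genes differed between labelled treatments more in parent than in knockout cells. Without parent labelled prexasertib replicate 1, which has 30.3% intronic reads, the interaction median was -1.276. That value argues against this library as the whole cause. With total counts only, which removes the composition factors, the interaction median was -1.243. Removing the factors shifted the interaction of all genes by a median of 0.0589, so they are too small to be the whole cause. With every library thinned to 47887791 exonic reads it was -1.33. Random thinning keeps the expected fold changes, so this value could hardly have moved and does not test depth as a cause. The SLFN11 genotype is the biological difference the design names. It may account for the pattern, but it was not tested apart from other differences between the knockout line and its parent, nor from a difference between cultures.

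Knockout and parent cells differed in the same direction under both labelled treatments for 3955 genes. Chromosome segments of unequal copy number could give such a pattern, and would shift whole stretches of genes. None of 290 windows of 10 Mb had a median beyond 0.4 in both comparisons, and 0% of the genes lay in such windows. The window medians reached from -0.6321 to 0.2342 under labelled DMSO and from -0.1774 to 0.229 under labelled prexasertib, which argues against large segments and leaves small ones open. The knockout of SLFN11 and clonal differences that arose when the line was made were not tested apart.

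Other splits of the samples were counted for each number of called genes. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. As many genes were called in 1 of 10 splits in parent cells (8374 genes, highest other split 0), in 1 of 10 in knockout cells (2982, highest other 0), in 1 of 10 between the lines under labelled DMSO (9212, highest other 1) and in 1 of 10 under labelled prexasertib (6467, highest other 0). For the interaction, 100 drawn splits with treatments reassigned within lines gave as many genes in 8, the real one with 3883 included, and the highest other gave 8089. All 8 kept the parent groups whole: 2 kept the knockout groups whole too, 1 of them with treatments exchanged in a single line, and 6 were among the 10 that mixed the knockout groups. The 11 splits that mixed only the parent groups called at most 4 genes, and the 77 that mixed both called 0. The large counts thus follow the structure of the parent groups, whose treatments differ whichever way the knockout libraries are split. That difference stays in the contrast of such splits, so the count of 8 neither excludes chance nor shows it for the interaction.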

How the results depend on the processing

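All alternatives here were planned, apart from the thinning of the libraries. Of 212 named gene values, 45 list medians, 10 counts and 4 intron shares, most kept direction and side of the threshold: 3539 of the gene values under alternatives did so, 24 lost their call, 1 gained one and 2 changed sign, and of counts 164 stayed within 1.5 times, 8 rose above that and 28 fell below it. Of list values 760 kept call and direction, 51 lost the call, 20 of them with the estimated correlation, 3 reversed and 1 gained a call. Most named genes were chosen for a small p or a large change in the main fit, and most lists for passing there. Their kept calls therefore say little about other genes and lists. Single genes got no value with files by library name, and 21 had too few reads outside other genes for that alternative. With files assigned by the library name in the title, the immediate early medians were 1.711 in parent cells, 0.3085 in knockout cells and 1.303 for the interaction, -0.1251 between the lines under DMSO and -1.306 under prexasertib, and lower counts between the lines were 3118 and 4697, by construction. Under glmTreat at 1.5-fold, higher and lower counts were 79 and 778 in parent cells, 8 and 119 in knockout cells, 615 and 924 between the lines under labelled DMSO, 448 and 391 under labelled prexasertib, and 10 and 200 for the interaction. In the same order, limma on TPM called 6364 and 2505, 1031 lower, 9197 and 1833, 6358 and 1327, and 2905 and 1128, and the interaction of SLFN11 and SLFN5, called in neither case, turned to 0.03071 and 0.01278. An adjusted p of at most 0.01 left 748 and 928 in knockout cells, 1961 lower between the lines under labelled prexasertib and 838 higher for the interaction. A fit of only the knockout groups called 2402 and 2476, and total counts only gave 2636 higher for the interaction. Unless construction shows it, the cause was not tested.

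Scaling moved the split of calls. The percent of calls that were higher went from 50, 49 and 43.4 in parent cells, between the lines under labelled DMSO and for the interaction to 62.2, 62.4 and 59.8 with total counts only. With TPM it went to 71.8, 83.4 and 72, and from 51.8 to 82.7 between the lines under labelled prexasertib. TPM shifted the median of all genes by 0.12, 0.25, 0.11 and 0.14 in those contrasts. The immediate early medians, past that size, also moved with TPM: from -1.711 to -0.8718 in parent cells, -0.3085 to -0.1897 in knockout cells, -1.306 to -0.54 between the lines under labelled DMSO and -1.303 to -0.5811 for the interaction, each still called. The cholesterol synthesis median in parent cells went from -0.3816 to -0.2012. The log2(TPM + 1) scale shrinks changes of low genes by construction, and how far this accounts for these moves was not tested. With an estimated correlation 25 of 45 list results held and 20 did not. Thinned to 47887791 exonic reads per library, the interaction called 1391 genes above 0 and 2410 below, against 1686 and 2197 in full, and lower depths were not tested.

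Leaving out each library in turn gave 2924 to 4030 higher and 3689 to 4604 lower genes in parent cells, 857 to 1134 and 1048 to 1292 in knockout cells, 3631 to 3921 and 4040 to 4529 between the lines under labelled DMSO, 2667 to 3337 and 2394 to 3124 under labelled prexasertib, and 954 to 2137 and 1800 to 2905 for the interaction. Immediate early medians ranged from -1.797 to -1.602, -0.3345 to -0.2857, -1.339 to -1.275, -0.1258 to -0.06186 and -1.389 to -1.253. With the replicate number as a block, counts were 4187 and 4194, 1415 and 1616, 4566 and 4715, 3370 and 3135, and 1745 and 2211, and medians were -1.716, -0.3087, -1.315, -0.1196 and -1.301. Same-numbered libraries had correlated deviations of 0.185, -0.01 and 0.145 between treatments in parent cells and -0.059, 0.07 and -0.163 in knockout cells, and not every sample correlated best with its own number.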

Other observations

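The list of hypoxia-type genes and the grouping by gene length in this part were chosen after gene values had been seen, and the test of intronic reads was planned before its result. Some genes known from the response to low oxygen differed between labelled treatments, but not all in the same direction. BHLHE40 was higher in labelled prexasertib, whose files carry the DMSO names, by 1.30 (SE 0.07) in knockout and 0.45 (SE 0.07) in parent cells. VEGFA was higher by 0.99 (SE 0.06) and 0.26 (SE 0.06), the glucose transporter gene SLC2A1 by 0.69 (SE 0.06) and 0.51 (SE 0.06), and the hexokinase gene HK2 by 0.56 (SE 0.08) and 0.64 (SE 0.08). The mitophagy gene BNIP3 differed by -0.61 (SE 0.06) in knockout cells and did not pass in parent cells, at -0.02 (SE 0.06, edgeR adjusted p = 0.81). SLC2A3 and CA9 passed with opposite signs in the lines, at 0.53 and -0.36 in knockout and -0.42 and 0.45 in parent cells. Of 30 genes of this kind, 14 were higher and 4 lower in parent cells (median 0.14, camera p = 0.0051, 0.016 with an estimated correlation). In knockout cells 11 were higher and 7 lower (median 0.01, camera p = 5.8e-06, 0.00092 with an estimated correlation). Without ADM, BHLHE40 and MIR210HG, which led to the list, camera p was 0.023 with a median of 0.10 in parent cells and 0.027 with a median of -0.07 in knockout cells, where the test pointed up and the median down. Over the 30 genes the interaction gave a camera p of 0.72, while by edgeR 8 members passed with a positive interaction and 6 with a negative one.

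The longest genes had the highest share of calls in the higher direction in labelled prexasertib. In parent cells this share never fell with length, while in knockout cells it fell from the shortest group to the next and then rose. The share of lower calls rose and then fell with length in both lines. Genes with a mean log2 CPM of at least 1 were put in 5 groups by span, with medians of 2.14, 10.9, 25.7, 50.9 and 133 kb. From the shortest to the longest group, 6.9, 5.4, 6.2, 9.4 and 19% were higher in knockout cells and 9, 14.3, 13.7, 9 and 3.9% were lower. In parent cells 24.2, 24.2, 25.3, 26.5 and 31.5% were higher and 19.4, 26.7, 30.7, 29.9 and 20.7% were lower, so the shortest group had the fewest lower genes there. These differences and their cause were not tested.

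A difference in transcription would change intronic as well as exonic reads of the immediate early genes. Over the 30 members with enough intronic reads, the median intronic log2 fold change in parent cells was -0.8886, against -1.504 for exonic reads of the same genes. It lay below 0 for 28 of 30 (93.3%), with 21 lower and 1 higher by edgeR. As a hypothesis, this is consistent with a change in transcription as part of the difference. In knockout cells the intronic median was -0.6865, against -0.1594 for exonic reads, with 24 of 30 below 0, 13 lower and 1 higher. The intronic interaction median was -0.4226, against -1.077 for exonic reads, with 22 of 30 below 0, 6 lower and 1 higher. The intronic and exonic values were not tested against each other, nor was a difference in RNA stability or in nuclear RNA. These introns can hold reads of overlapping or antisense genes.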
